A study of Homo sapiens with 6 samples.

How the data were processed

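RNA from 6 cultures of the human ovarian cancer line ES2 was measured by RNA sequencing after 7 days, with 1 library in each of the groups Control, T, G, R, TR and GR. Groups were taken from the sample titles. The titles all give ES2, while the source names of G, R, TR and GR give SKOV3, a conflict that stays open in the labels. Per the labels' protocols, mRNA was purified with oligo(dT) beads and made into strand-marked (dUTP) libraries read as 150-base pairs. The labels name different sequencers in different fields. The submitters' processing notes name cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR without saying which made which value. The genome build and annotation are not given in the sources used here.

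The deposited table holds 33706 genes with a read count and an FPKM per library, per the file headers. The authors' counts are whole numbers and were used as deposited. The authors' FPKM values, fragments per kilobase of transcript scaled to library depth, were also used as deposited. No column of per-sample values was left unused. Of the gene identifiers 92.6% are in GENCODE v29, and 99.94% of those overlap its coordinates on GRCh38, so the coordinates printed are those of the table. Of the genes 8586 have no symbol, 698 share a symbol and 10485 overlap another gene on the same strand. How reads of overlapping genes, readthrough genes, paralogs and pseudogenes were divided is not given in the sources used here, so such genes are reported as uncertain.

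Library totals ran from 73213048 to 83976498 counts. A count of 0 allows a share of up to 4.1e-06% of the smallest library (3 counts). Shares of counts have 95% Wilson intervals. The libraries carry no molecular identifiers, so intervals and floors cover counting error only. No pair of libraries was alike within sampling noise. The smallest chi-square per degree of freedom was 103.1, for R and TR.

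For pairs of libraries, the log2 ratio of FPKM + 1 was taken, which understates changes of low genes, and genes at 2-fold or more were counted among the 13259 genes with an FPKM of at least 1 in a library. With 1 library per group these have no test. The ratios of the pairs that share no library stand for repeats: R against Control, TR against T and GR against G for R, T against Control and TR against R for T, and G against Control and GR against R for G. Values given as mean ± SD for R are over the 3 pairs.

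Across backgrounds, an additive model of oligo (none, T, G) and R was fitted to the counts with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. It tested 20922 genes with 2 residual degrees of freedom. The labels do not say that the cultures were set up separately, so p-values measure only the spread between these libraries. Gene lists fixed before the data were examined, 28 in number, were tested, apart from the cell line check, with camera (preset correlation 0.01 and estimated correlation) and fry in limma 3.58.1. All but the cell line check and the leukocyte markers were described by the percentile of their median among 10000 random lists of the same size matched on mean expression in 20 bins. In simulated data 1.5% of 200 unchanged lists lay outside the central 95%. The simulated genes varied independently, while members of real lists vary together (estimated correlation 0.822 for mitosis genes in the test for R). The percentiles therefore describe these libraries and are no test. The lists cover telomere maintenance, DNA damage, G-quadruplex helicases and promoters, S phase, mitosis, secretory, interferon, NF-kB and nucleic acid sensing genes, apoptosis, autophagy, stress responses, cholesterol synthesis, hypoxia, mesenchymal, epithelial and immediate early genes, histones, mitochondrial, ribosomal and respiratory genes, leukocyte and endothelial markers and cell line checks. The leukocyte list had 5 tested members. Some genes and 1 list that these rules take in are not reported here.

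Named genes follow a rule fixed together with the lists. For R, T and G across backgrounds it takes the 12 highest and 12 lowest called genes with a symbol of their own, an FPKM of at least 5 and the same sign in every pair that shares no library, filled where fewer were called with genes ranked by their smallest ratio among those pairs. It adds the 5 highest and 5 lowest ratios of each pair, 4 members of each list with the largest coefficient, and, among others, ERBB2, CDKN2A, CDKN1A, TERT, TERF1, TERF2, POT1, E2F1 and MYC. MT-RNR1, MT-RNR2, MT-ND1, MT-CYB, ADORA2A, SPECC1L-ADORA2A, BIVM-ERCC5 and ABCA11P were named after their values were seen.

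The edgeR step was tested on simulated counts for the 20922 genes with 200 genes changed for R. At the common dispersion of 0.14 it recovered 6% of genes changed 2-fold, 72% of those changed 4-fold and 100% of those changed 8-fold or 16-fold, with 0 false calls. At the median genewise dispersion of 0.101 these were 16%, 94% and 100%, with 5 false calls. Alternatives were other pseudocounts, filters and scalings, limma on log2 FPKM, DESeq2 1.42.0, models without the oligo term or with the source-name cell line, and the fit without each library in turn. Chosen after seeing the data were the removal of a trend with GC content and transcript length (splines with 5 degrees of freedom per variable, longest GENCODE v29 transcript, 97.1% of genes with a value), the restriction to genes with a symbol and no same-strand overlap, and the fit without mitochondrial genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for the lists, tests of explanations and figures.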

Results

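RNA was sequenced from 6 cultures of the ovarian cancer line ES2 after 7 days, 1 library per group. The groups were an untreated control, cultures with T, with G (described in the labels as G4) and with R, and cultures labelled TR and GR, read here as combinations. The study concerns T-oligos, DNA oligonucleotides modelled on the telomere overhang, and RHPS4, a ligand of G-quadruplexes. The labels do not spell out T and R, so the letters are kept. T and G are read here as oligos and R as the other factor, which the labels do not settle. The library totals were 80880921 counts for the control, 73213048 for T, 78683454 for G, 83221578 for R, 79705117 for TR and 83976498 for GR. No group had a replicate, so a difference between a pair of libraries has no replicate check. The 3 backgrounds (no oligo, T and G), each without and with R, served as the repeats for R. T and G were each measured in 2 backgrounds.

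The source names of the G, R, TR and GR libraries give SKOV3, another ovarian cancer line, while all 6 titles give ES2. ERBB2, the receptor gene that is amplified in SKOV3 cells, lay between 0.146 and 0.721 FPKM in all 6 libraries. CDKN2A lay between 74.4 and 146 FPKM. Neither gene separated the libraries whose source name gives SKOV3 from the control and T. The low ERBB2 levels argue against SKOV3 cells in G, R, TR and GR.

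The comparison of R across the 3 backgrounds asks which genes differ with R whichever oligo is present. Mitochondrially encoded transcripts fell in every background. All 13 mitochondrial mRNAs were called lower, 13 also when adjusted over the list alone, with a median log2 fold change of -4.69. MT-CO3, which encodes a subunit of cytochrome c oxidase (ENSG00000198938, mitochondrial genome 9207 to 9990, plus strand), fell from 6815, 4286 and 4774 FPKM in control, T and G to 44.8, 41.8 and 91.4 FPKM in R, TR and GR. Its log2 ratio was -6.52 ± 0.77 (SD, n = 3 pairs of libraries; edgeR quasi-likelihood adjusted p = 8.67e-05). MT-ND4, a complex I subunit, had a ratio of -6.37 ± 0.76, and MT-CO1, another subunit of cytochrome c oxidase, one of -5.37 ± 0.64 (SD, n = 3 pairs each). MT-CO3 and MT-ND4, like MT-TY and MT-ND4L, overlap a neighbouring gene on the same strand by their coordinates, and MT-CO1 does not.

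The loss was uneven along the mitochondrial genome. The 12S ribosomal RNA MT-RNR1 stood at 0.25 ± 0.34 and was not called (adjusted p = 0.178), while the 16S ribosomal RNA MT-RNR2 fell by 2.01 on the log2 scale (SE 0.19, adjusted p = 0.00268). MT-ND1, the mRNA nearest to the ribosomal genes, stood at -3.41 ± 0.28, and MT-CYB, the most distal on that strand, at -3.82 ± 0.94 (SD, n = 3 pairs). The mitochondrial tRNAs MT-TD, MT-TL1, MT-TY, MT-TN, MT-TA and MT-TS1 were among the 12 most strongly lowered named genes, with log2 fold changes from -6.51 for MT-TD to -5.01 for MT-TS1. MTCO1P12, a nuclear pseudogene copy of MT-CO1, fell with them (log2 fold change -4.92, SE 0.31), and reads of such near-identical copies may be shared. Mitochondrial genes took 6.98% of counts in the control (95% Wilson interval 6.973 to 6.984), 5.44% in T and 6.17% in G, against 0.351% in R (0.350 to 0.3525), 0.474% in TR and 0.893% in GR. These intervals cover counting error only.

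**Figure D1:**
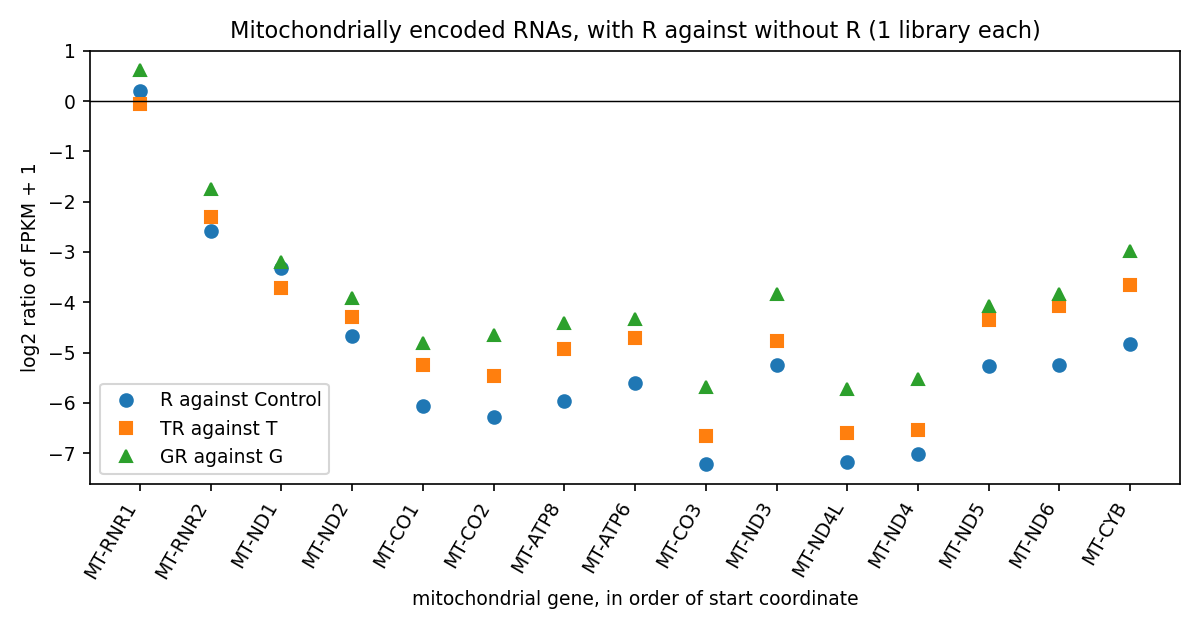
Log2 ratio of FPKM + 1 with R against without R (vertical axis) for each mitochondrially encoded rRNA and mRNA in order of its start coordinate (horizontal axis), each point a ratio of 2 libraries, R against Control (circles), TR against T (squares) and GR against G (triangles). MT-RNR1 lies between -0.06 and 0.61, and MT-CO3 between -7.22 and -5.69.

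Among nuclear genes, members of several lists were called higher with R. No list held for R as a list with an estimated correlation (camera, smallest adjusted p = 0.723) or with fry. The smallest fry adjusted p was 0.0765, shared by the mitochondrially encoded list and the G-quadruplex helicases, both lower. For the histones fry gave an adjusted p of 0.429 and for the secretory list one of 0.471. The estimated setting had little power here. It gave the mitochondrially encoded list, with all 13 mRNAs called, an unadjusted camera p of 0.0176. A list that did not hold may therefore still have changed. The replication-dependent histone genes called included H2AC19 (log2 fold change 3.83, SE 0.67, adjusted p = 0.0378), H1-2 (2.72, SE 0.49) and H2BC12 (1.96, SE 0.29). In that list 5 of 18 tested members were called higher and 6 when adjusted over the list alone. With oligo(dT) capture, a change in polyadenylation of the histone transcripts cannot be told apart from a change in their amount. ZFP36, an RNA-binding protein that destabilises inflammatory mRNAs, rose by 3.22 (SE 0.51, adjusted p = 0.0302), and MMP3, a matrix metalloproteinase, by 2.99 (SE 0.50, adjusted p = 0.0358). The circadian repressor NR1D1 rose by 2.69 (SE 0.38), the transcription factors HES1 and CEBPD by 2.78 (SE 0.55) and 2.54 (SE 0.51), and the cell cycle inhibitors CDKN2D and CDKN1A by 2.66 (SE 0.46) and 1.60 (SE 0.33, adjusted p = 0.0488). The rises of H2AC19, ZFP36 and NR1D1 were larger in R against control (3.98, 2.95 and 2.74) than in GR against G (1.25, 1.24 and 1.14), a difference that was not tested. By source name, GR against G is the only R pair within 1 cell line. H2AC19 and H2AC18 are near-identical copies and are uncertain, as are SLC2A3 and TNFRSF6B, which overlap other genes on the same strand. The readthrough gene INO80B-WBP1 had 0 counts in the control, T and G and 1219 to 2516 counts with R, at least 395-fold higher in R than in the control against a floor of 3 counts, and its assignment is uncertain.

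Fixed gene lists gave further members that passed the test for R. In the hypoxia and glycolysis list, 4 of 28 were called higher (10 adjusted over the list alone), among them the glucose transporter genes SLC2A3 (2.61, SE 0.38) and SLC2A1 (1.75, SE 0.30), both of which overlap another gene on the same strand. In the NRF2 and oxidative stress list, 3 of 22 were called (6 higher and 1 lower adjusted over the list alone), among them the quinone reductase NQO1 (1.48, SE 0.25). In the immediate early list, 3 of 24 were called (11 higher and 1 lower adjusted over the list alone), ZFP36 and KLF6 (1.65, SE 0.29) among them. In the secretory list 5 of 30 were called higher (11 higher and 1 lower adjusted over the list alone), although the median of that list was -0.30 in GR against G (percentile 0.01), and in the mesenchymal list 2 of 30 (13 higher and 2 lower adjusted over the list alone), SNAI1 (2.43, SE 0.35) and the matricellular gene CCN1 (1.41, SE 0.22). The autophagy and lysosome list had 1 called member, GABARAPL1 (1.52, SE 0.26), and 9 adjusted over the list alone. The sterol transport gene STARD4 fell by 1.84 (SE 0.29, adjusted p = 0.0298), the only called member of the cholesterol synthesis list. Of the NF-kB targets, BCL3, which overlaps another gene on the same strand, rose by 2.26 (SE 0.32) and the maturation marker CD83 fell by 1.93 (SE 0.38), the only called members of 18, with 2 higher and 3 lower adjusted over the list alone. Each nuclear gene named so far for R, other than INO80B-WBP1 and MTCO1P12, lost its call when 1 library was left out. H2AC19, ZFP36, MMP3, HES1, CEBPD, CDKN1A, SNAI1, CCN1, KLF6, GABARAPL1 and CD83 lost it without any 1 of control, R, T and TR. TNFRSF6B lost it without the control and without R, and STARD4 and NQO1 without T and without TR. Leaving out either library of a pair removes the whole pair from the estimate for R, so these are losses by pair.

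The additive edgeR quasi-likelihood model called 523 of 20922 genes for R, 248 higher and 275 lower, 31 of them mitochondrial, and 5681 genes had an unadjusted p under 0.05. Leaving out 1 library removes its whole pair from the estimate for R, because its partner is then alone at its oligo level. The median log2 fold change of the 13 mitochondrial mRNAs was -4.33 without the control or without R. It was -4.84 without T or without TR and -4.9 without G or without GR. How many genes were called depended strongly on which pair was left out. By source name, R against control and TR against T also change cell line. With that line as a term, R is estimated from GR against G alone, 1 library each. That fit called 82 genes, 46 of them among the 523. With 2 residual degrees of freedom, the p-values of the model without that term measure only the departure from additivity between the 6 libraries.

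In the pairs of libraries, R against control had 1232 of 13259 genes at least 2-fold different, 355 higher and 877 lower (455 and 704 with median-ratio scaling). TR against T had 2239, 752 higher and 1487 lower, and GR against G had 448, 173 higher and 275 lower. The 3 pairs share no library. Across genes, which are not independent replicates, the log2 ratios of R against control correlated with those of TR against T at r = 0.634 (covariance 0.3176) and with those of GR against G at r = 0.491 (covariance 0.1602), and TR against T with GR against G at r = 0.668 (covariance 0.26). In all 3 pairs 54 genes were at least 2-fold higher, against 0.26 for independent lists, and 81 were lower, 34 of them mitochondrial, against 2. The genes with the highest ratios in R against control included DUSP1, a phosphatase of MAP kinases, at 1133 against 72.0 FPKM, and the stress cytokine GDF15, which overlaps another gene on the same strand, at 29.3 against 1.54 FPKM. In GR against G, UBALD2 stood at 55.4 against 14.96 FPKM.

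The comparison of T asks which genes differ with T, without R (T against control) and with it (TR against R). Without R, cell cycle genes were much lower with T. TYMS, thymidylate synthase, stood at 10.1 FPKM in T against 98.8 FPKM in the control, a log2 ratio of -3.17, and TK1, thymidine kinase, at 6.10 against 43.9 FPKM (-2.66). The mitotic kinesin KIF20A had a ratio of -2.52, the cell cycle transcription factor FOXM1 one of -2.20 and CDC20, an activator of the anaphase-promoting complex, one of -2.11. Of 30 G2/M and mitosis genes 26 were at least 2-fold lower and none higher, with a median log2 ratio of -1.54, below all of 10000 random lists matched on expression (percentile 0.00, a description of these libraries). Of 30 S phase genes 12 were at least 2-fold lower, with a median of -0.97 (percentile 0.00).

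Stress genes lay in the other direction in T against control. ASNS, asparagine synthetase and a target of ATF4, which overlaps another gene on the same strand and is uncertain, stood at 123 against 17.7 FPKM (2.73), GDF15 at 19.7 against 1.54 FPKM (3.02) and the activin subunit INHBE at 10.2 against 0.529 FPKM (2.87). DDIT4, CHAC1 and TRIB3, further genes of the integrated stress response, had ratios of 2.49, 1.88 and 1.93. Of 26 members of the unfolded protein and integrated stress list 9 were at least 2-fold higher and 1 lower, with a median of 0.72 (percentile 100). The heat shock list had a median of -0.68 (percentile 0.04), with HSPA1A at -1.14.

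With R present, the cell cycle and integrated stress lists differed little, and the heat shock list stayed lower, with a median of -0.31 in TR against R (percentile 0.02; -0.47 with a GC and length trend removed). In TR against R, the mitosis list had a median of -0.04 (percentile 4.98; 0.01 with that trend removed), the S phase list 0.01 (percentile 23.04; -0.02 with the trend removed; -0.58 in R against control) and the unfolded protein and integrated stress list 0.08 (percentile 64.90). TYMS had a ratio of 0.02, KIF20A 0.38, and ASNS 0.27, while TRIB3 was 2-fold higher (1.01). T against control had 623 genes at least 2-fold different, 318 higher and 305 lower, and TR against R had 112, 61 higher and 51 lower. Across genes the ratios of the 2 pairs correlated at r = -0.086 (covariance -0.0139). These pairs had opposite trends with GC content (Spearman -0.29 in T against control and 0.6 in TR against R). The correlation was not computed with that trend removed. Genes with a symbol that lay in the same direction in both pairs included CXCL2 (1.03 and 1.15), CEBPB (0.94 and 0.99), ATOH8 (0.79 and 1.03), ANLN (-1.86 and -0.76), DLGAP5 (-1.49 and -0.66) and DHX9 (-0.81 and -0.62), none of which was called.

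Across backgrounds, 1 of 20922 genes was called for T, KRT85, and 767 had an unadjusted p under 0.05. KRT85, a hair keratin gene (ENSG00000135443, chromosome 12, 52360006 to 52367481, minus strand), had 0 counts in the control and R, 4067 in T, 5076 in TR, 1333 in G and 3310 in GR. Against a floor of 3 counts it was at least 1498-fold higher in T than in the control and at least 1767-fold higher in TR than in R. Hair keratin genes are close paralogs, so the assignment of these reads is uncertain. The count was 2 without the control, 6 without T, 50 without G, 10 without R, 26 without TR and 26 without GR.

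The comparison of G asks the same with G in place of T. Several inflammatory and secretory genes were higher with G in both backgrounds. CCL2, a chemokine for monocytes, stood at 21.4 FPKM in G against 2.18 in the control and at 13.8 in GR against 1.54 in R, log2 ratios of 2.82 and 2.54. IL7R, the interleukin 7 receptor (ENSG00000168685), was called higher (log2 fold change 3.12, SE 0.36, adjusted p = 0.0472), a call lost without the control and without R, and so was C1QTNF1, a secreted protein with a C1q domain (ENSG00000173918; 5.29, SE 0.38, adjusted p = 0.00213), with 52, 544, 2264, 28, 312 and 1435 counts in control, T, G, R, TR and GR. CSF1, a growth factor of macrophages, had ratios of 1.76 and 1.54, the matrix glycoprotein THBS1, which overlaps another gene on the same strand, 2.30 and 2.01, and the tight junction gene CLDN1 2.84 and 1.54, without being called. The chemokine CXCL1 stood at 159.9 FPKM in G against 15.4 in the control (3.29), and the cytokines IL1A and IL6 had ratios of 3.07 and 2.66 in G against control and of 0.95 and 1.33 in GR against R. CXCL2 was higher without R only, at 13.97 FPKM in G against 2.77 in the control and 2.56 in GR against 2.44 in R. By source name, G against control also changes cell line, and GR against R does not.

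Of 27 secretory genes measured 14 were at least 2-fold higher in G against control, with a median of 1.10 (percentile 100). In GR against R 5 were higher and 1 lower, with a median of 0.38 (percentile 98.96), or 0.25 with median-ratio scaling. Of 17 NF-kB targets 11 and 4 were higher, with medians of 1.06 (percentile 100) and 0.66 (percentile 99.86). With T the same lists lay in the same direction, with secretory medians of 0.26 in T against control (percentile 98.78) and 0.38 in TR against R (percentile 100) and NF-kB medians of 0.37 (percentile 99.63) and 0.51 (percentile 100). IL32 and BIRC3 had the highest ratios of that list in G against control (2.06 and 2.05), and IL32 overlaps another gene on the same strand. Of 22 interferon-stimulated genes 7 and 6 were higher, with medians of 0.46 (percentile 99.87) and 0.39 (percentile 81.92), among them IFIT3 (1.18 and 1.18), BST2 (1.64 and 1.18) and SAMD9 (1.07 and 1.92). In the fit across backgrounds no member of these 3 lists was called over all genes, while 11 secretory genes, 7 NF-kB targets and 5 interferon-stimulated genes were called higher, and 1 secretory gene lower, adjusted over the list alone. By camera with a preset correlation the 3 lists were higher (adjusted p = 2.57e-05, 1.5e-05 and 1.03e-05), and none of the 38 calls among 81 list tests held with an estimated correlation (smallest adjusted p = 0.723). The mitochondrially encoded list for R did not hold in that setting either, so a list that did not hold may still have changed.

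Fewer genes were 2-fold lower than higher with G in both backgrounds. The antisense gene VIM-AS1 had ratios of -1.57 and -2.83, MRPL53, a mitochondrial ribosomal protein gene that overlaps another gene on the same strand, -2.01 and -1.63, and the globin gene HBD -1.54 and -1.30. RGS3, a regulator of G protein signalling, had ratios of -1.21 and -1.84, TAGLN3 -1.16 and -1.01, AOX1, aldehyde oxidase, -1.25 and -0.87, and AK5, an adenylate kinase, -0.83 and -0.98, none of them called. Ribosomal protein genes had a median of -0.14 in G against control (percentile 92.67; -0.08 with the GC and length trend removed) and of -0.51 in GR against R (percentile 0.00), and none of 74 differed 2-fold. G against control had 494 genes at least 2-fold different, 434 higher and 60 lower. GR against R had 968, 823 higher and 145 lower, which median-ratio scaling turned into 524 and 242, with a shift of the median of all genes by -0.15. The ratios of the 2 pairs, which share no library, correlated across genes at r = 0.279 (covariance 0.0674), with 98 genes higher in both against 26.9 for independent lists and 14 lower in both against 0.7. The edgeR quasi-likelihood test called 7 of 20922 genes for G, 5 higher and 2 lower, and 2492 had an unadjusted p under 0.05. The count was 12 without the control, 33 without T, 337 without G, 16 without R, 29 without TR and 127 without GR. Besides C1QTNF1 and IL7R the 7 were KRT85, ABCA11P, BIVM-ERCC5, SPECC1L-ADORA2A and ADORA2A, of which the last 4 overlap another gene on the same strand or are readthrough genes and are uncertain. ABCA11P is also a symbol shared by more than 1 gene, and it lost its call without the control.

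**Figure D2:**
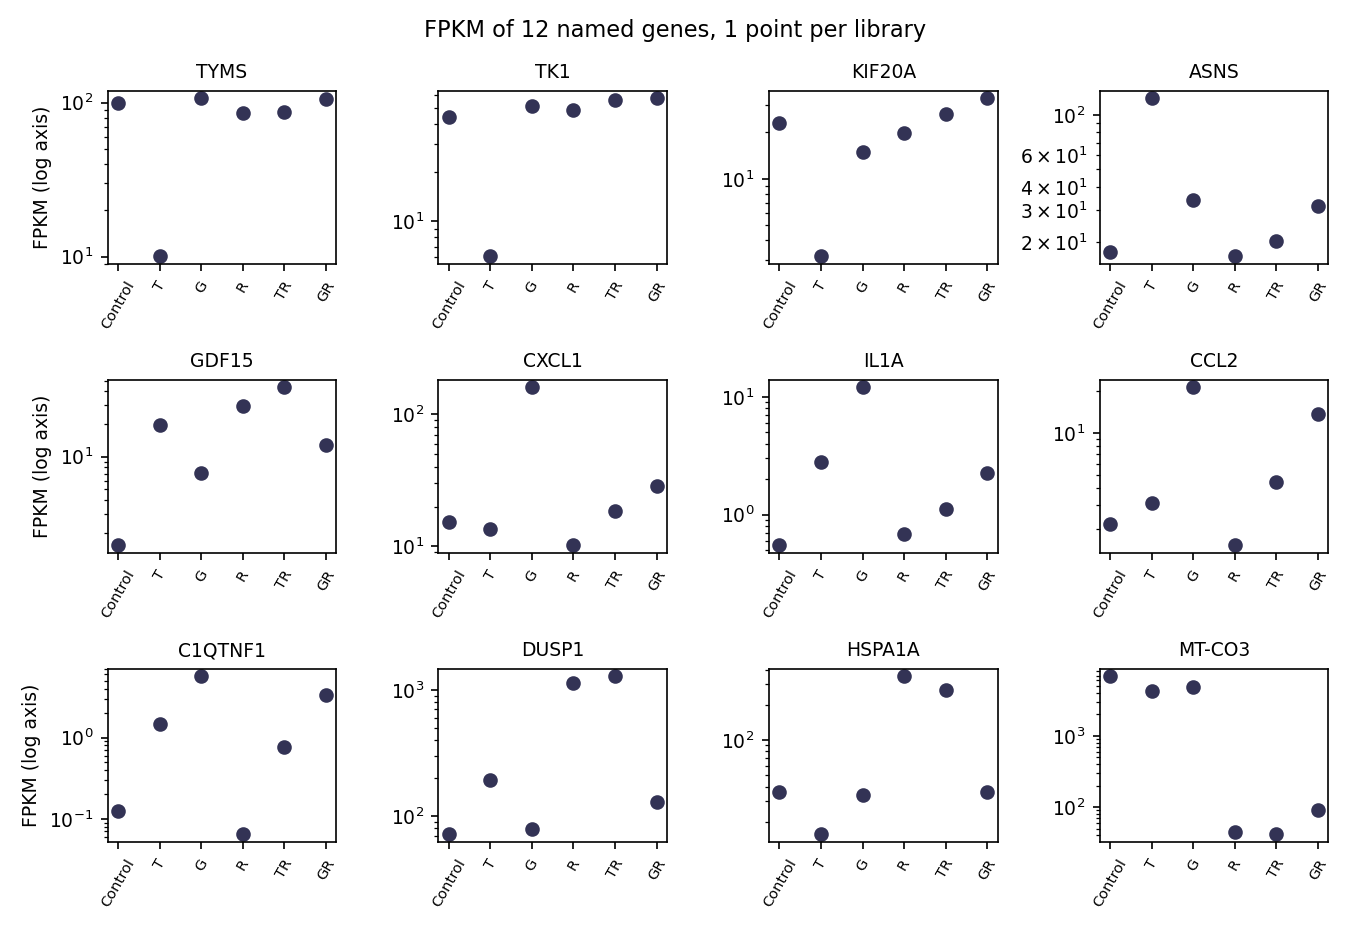
FPKM on a log axis (vertical) of 12 named genes in each library (horizontal, 1 point per library). TYMS lies at 10.1 FPKM in T and at 85.6 to 106.5 FPKM in the other 5 libraries, and CXCL1 is highest in G at 159.9 FPKM.

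Set directly against each other without R, G had higher cell cycle genes than T, in a pair that by source name also changes cell line. In G against T, TYMS stood at 106.5 against 10.1 FPKM (3.28), the proliferation factor MYBL2 at 23.6 against 1.88 FPKM (3.10) and TK1 at 51.1 against 6.10 FPKM (2.88). The mitosis list had a median of 1.24 with 25 of 30 members at least 2-fold higher, and the S phase list one of 1.16 with 19 of 30. CXCL1 was also higher in G (3.46), while ASNS (-1.82, uncertain by its overlap), INHBE (-2.04) and the steroidogenic enzyme gene CYP11A1 (-2.51) were lower. This pair had 546 genes at least 2-fold different, 414 higher and 132 lower. Across backgrounds the edgeR quasi-likelihood test called 3 genes, SPECC1L-ADORA2A, BIVM-ERCC5 and ADORA2A, all of uncertain assignment, of which ADORA2A lost its call without T and without TR, with 1244 at an unadjusted p under 0.05. The count was 7 without the control, 8 without T, 107 without G, 16 without R, 12 without TR and 58 without GR.

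The combined treatments were also set against the control. TR had 969 genes at least 2-fold different, 435 higher and 534 lower (502 and 438 with median-ratio scaling), led upward, apart from KRT85, by genes also higher in R alone, such as DUSP1 (1278 against 72.0 FPKM) and GDF15 (43.2 against 1.54 FPKM). GR had 616, 433 higher and 183 lower, with IGFBP7, an insulin-like growth factor binding protein, at 62.1 against 4.15 FPKM, THBS1 at 41.1 against 3.51 FPKM and the collagen receptor MRC2 at 27.6 against 2.52 FPKM. Both THBS1 and MRC2 overlap another gene on the same strand and are uncertain. The lowest genes were mitochondrial in both, with MT-CO3 at -7.32 in TR and MT-ND4L at -6.38 in GR. These comparisons share the control library with those of T, G and R. Of all pairs, R and TR were the most alike, with r = 0.983 across genes, although their counts differed by far more than sampling noise (chi-square of 103.1 per degree of freedom).

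**Figure D3:**
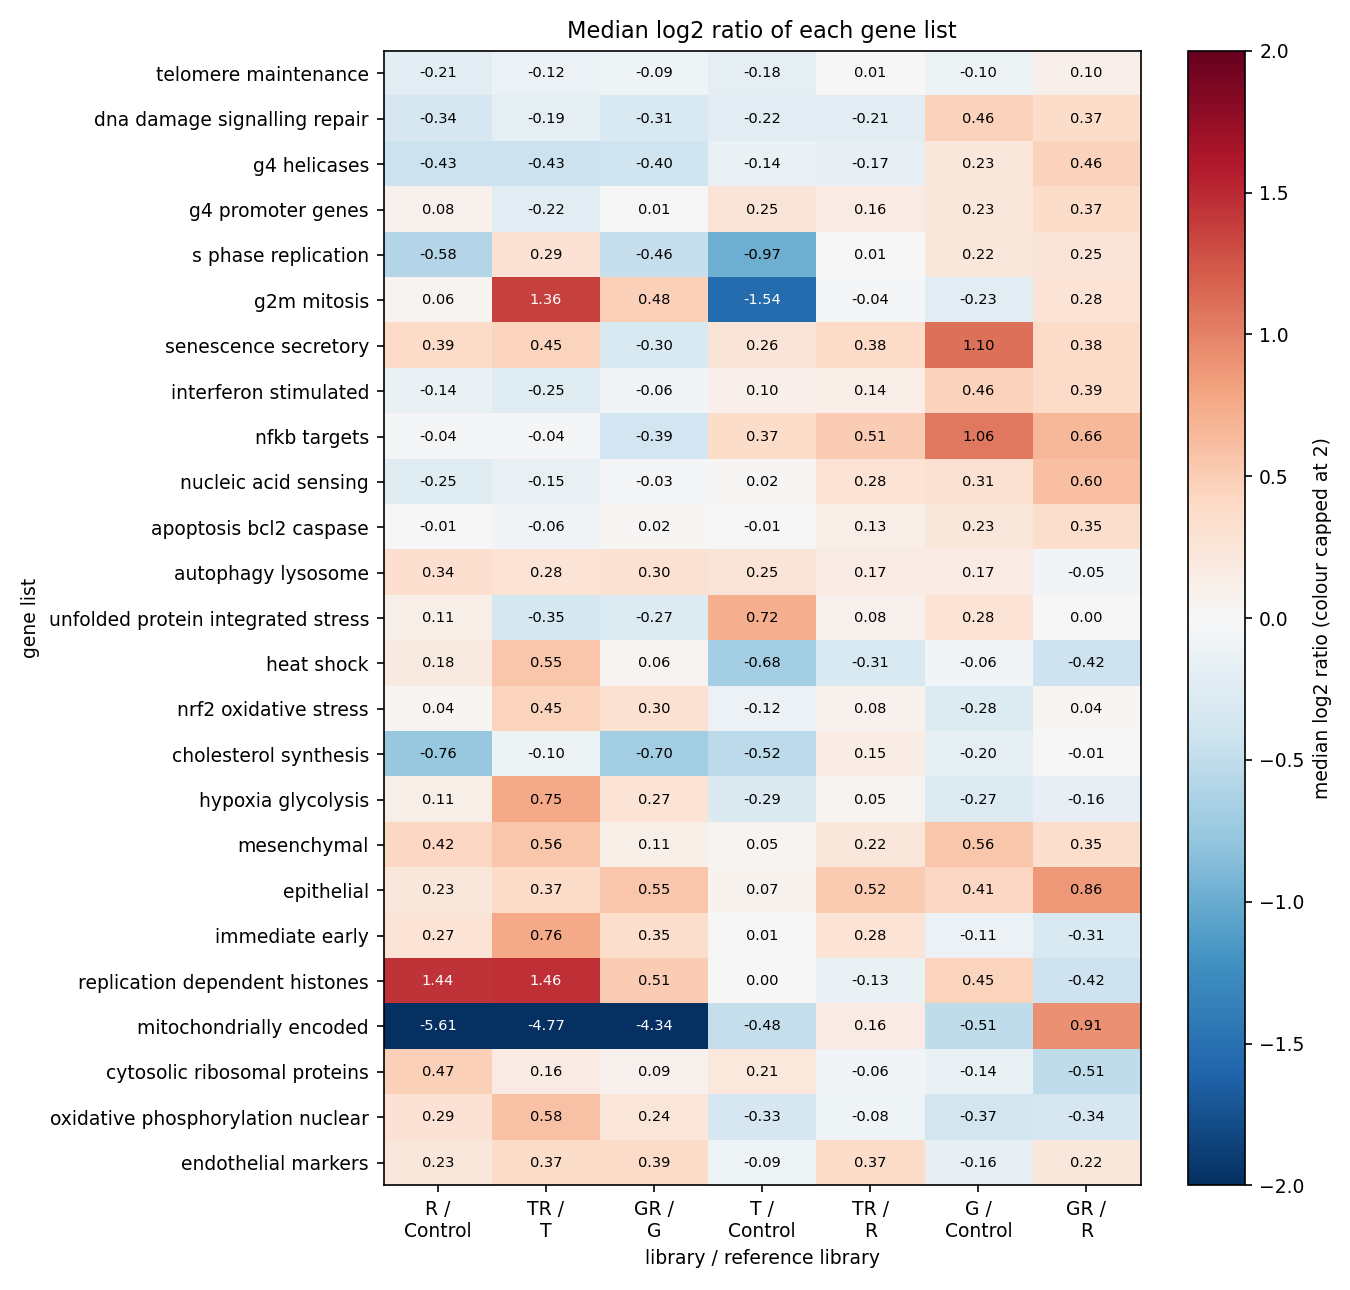
Median log2 ratio of FPKM + 1 (printed value, with the colour capped at 2) of the gene lists reported (vertical axis) in 7 pairs of libraries (horizontal axis, library over reference library, 1 library each). The mitosis list reads -1.54 in T over Control and -0.04 in TR over R, and the mitochondrially encoded list lies between -5.61 and -4.34 in the 3 pairs with R over without R.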

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

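No tests in this part were chosen after the results were seen, and it gives medians of fixed gene lists that pointed in opposite directions where the same treatment was compared in different backgrounds. None of these differences was tested, since each median comes from 1 pair of libraries. The 74 cytosolic ribosomal protein genes had a median log2 ratio of 0.21 in T against control (percentile 99.99 among random lists) and of -0.06 in TR against R (percentile 0.84). The 13 mitochondrially encoded mRNAs had a median of -0.51 in G against control (percentile 0.48) and of 0.91 in GR against R (percentile 100). The 27 secretory genes had a median of 0.39 in R against control (percentile 99.95) and of 0.45 in TR against T (percentile 99.54), against -0.30 in GR against G (percentile 0.01). No group had enough libraries to look for a library far from the others of its group.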

How the results depend on the processing

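Chosen after the data were seen were the removal of the GC and length trend, the restriction to genes with a symbol and no same-strand overlap, and the fit without mitochondrial genes. No paired analysis was possible because, with 1 library per group, the groups share fewer than 2 replicate numbers. The comparison of R was matched on oligo background instead.

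The counts of genes at least 2-fold different kept within 1.5 times of their value with median-ratio scaling and with the GC and length trend removed. Leaving out the filter on low values could not change them, since at a pseudocount of 1 a gene under an FPKM of 1 in every library cannot differ 2-fold. With a pseudocount of 0.1 they were larger, because low genes then count more: 1570 for T against control, 1361 for G against control, 2820 for R against control, 2460 for TR against control, 1442 for GR against control, 4104 for TR against T, 521 for TR against R, 1270 for GR against G, 2587 for GR against R and 1210 for G against T. The genes 2-fold different the same way in all 3 R pairs then numbered 490 against 135. With fewer genes counted, those with a symbol and no overlap, the counts in the same order were 392, 249, 784, 623, 379, 1452, 28, 237, 601 and 354. With an FPKM of at least 5 in a library, 3 counts moved by more than 1.5 times, to 274 for G against control, 70 for TR against R and 296 for GR against G.

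The counts across backgrounds depended on the tool and the filter. For R, edgeR called 523 genes, limma on log2(FPKM + 1) 1838, limma with a pseudocount of 0.1 1612, limma with median-ratio scaling 1938, limma with the GC and length trend removed 1246 and DESeq2 3721. With no filter on low counts edgeR called 24 for R and 0 each for T, G and G against T (unadjusted p under 0.05 for 5233, 642, 2237 and 1094), and limma with no filter called 0 for each (5709, 849, 3335 and 2333). Leaving out the oligo term gave 298 for R. The source-name cell line as a term gave 82, of which 46 were among the 523, but R is then estimated from GR against G alone. For T the count was 1 with edgeR, 2 with limma, with limma at a pseudocount of 0.1 and with median-ratio scaling, and 28 with DESeq2. For G it was 7 with edgeR, 24 with limma, 420 with DESeq2 and 1 with the GC and length trend removed. For G against T it was 3 with edgeR, 5 with limma and median-ratio scaling, 94 with DESeq2 and 0 with the GC and length trend removed (1043 at an unadjusted p under 0.05). The cause of these differences was not tested. With DESeq2 size factors in edgeR, and with mitochondrial genes left out, all 4 counts stayed within 1.5 times. Of 81 list tests camera called 38 with a preset correlation and 0 with an estimated one (1 at an unadjusted p under 0.05), and fry called 0 (smallest adjusted p = 0.0765).

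Without each library in turn, with the lone sample of a group assumed to vary like the other groups, the count for R ran from 66 without the control to 2231 without G, for T from 2 without the control to 50 without G, for G from 12 without the control to 337 without G and for G against T from 7 without the control to 107 without G. For R, each of these fits drops a whole pair, since the partner is then alone at its oligo level. No called gene changed sign. The 13 mitochondrial mRNAs were called lower for R in each of these fits and in every other setting except with no filter on low counts or values, where edgeR called 11 and limma 0. Their median log2 fold change ran from -4.90 to -4.27 over the settings. The effect of depth on the calls was not tested. In simulated data for R, genes changed 2-fold were recovered at 6% with a dispersion of 0.14, so the absence of a call says little about changes of that size.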

Other observations

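The tests chosen only after the result was seen were those of an equal loss of mitochondrial RNA, of distance from the promoter, of TR as a second R library, of the mitosis genes with R alone and of leukocyte transcripts, and the criterion of the test of TR was changed after its result was seen.

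Some heat shock and immediate early genes were high in R and TR and not in GR. HSPA1A, an inducible chaperone, stood at 349.7 FPKM in R, 267.0 in TR and 36.0 in GR, against 35.8 in the control, 15.7 in T and 34.2 in G, and its near-identical copy HSPA1B, which also overlaps another gene on the same strand, had a log2 ratio of 3.30 in R against control and of 0.06 in GR against G. The transcription factor FOS stood at 25.8 FPKM in R, 21.1 in TR and 2.28 in GR, against 1.33 in the control. The medians of the heat shock list were 0.18, 0.55 and 0.06 in R against control, TR against T and GR against G, and those of the immediate early list 0.27, 0.76 and 0.35 (percentiles 96.26, 99.99 and 98.88). With the GC and length trend removed, an alternative chosen after seeing the data, these were 0.24, 0.30 and -0.13 for heat shock, and 0.33, 0.46 and 0.12 for immediate early genes (percentiles 99.25, 99.79 and 62.87). Cholesterol synthesis genes had medians of -0.76, -0.10 and -0.70 in these pairs (-0.72, -0.30 and -0.62 with the trend removed) and of -0.52 in T against control. Nuclear genes of oxidative phosphorylation had medians of 0.29, 0.58 and 0.24 with R, of -0.33 in T against control and of -0.37 in G against control (0.18, 0.52, 0.29, -0.34 and -0.34 with the trend removed).

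Of the lists nearest to the study's subject, telomere maintenance genes had medians of -0.18 in T against control, -0.10 in G against control and -0.21 in R against control (-0.11 for R with median-ratio scaling). TERT, the catalytic subunit of telomerase, stood at 0.899 FPKM in the control, 1.096 in T and 1.273 in G. With R it stood lower, at 0.406 FPKM in R, 0.601 in TR and 0.509 in GR, all of them low levels. DNA damage genes had medians of -0.22, 0.46 and -0.34 in these pairs, G-quadruplex helicases -0.14, 0.23 and -0.43 and genes with G-quadruplex promoters 0.25, 0.23 and 0.08 (0.20 for R with median-ratio scaling). With the GC and length trend removed, the telomere maintenance medians were -0.03, -0.03 and -0.28, those of DNA damage genes -0.25, 0.28 and -0.29 (percentiles 0.00, 99.89 and 8.11), those of the helicases -0.11, 0.11 and -0.37 and those of the promoter genes 0.25, 0.27 and 0.14. The helicases had medians of -0.43 in TR against T and -0.4 in GR against G (-0.3 and -0.27 with the trend removed, percentiles 14.1 and 0.75). Of 12 tested helicases 0 were called for R over all genes, and 3 were lower adjusted over the list alone. By fry the helicase list was lower for R and for T (adjusted p = 0.0765 each) and higher for G (adjusted p = 0.429), none of them a call. The DNA damage genes had medians of -0.21 in TR against R and 0.37 in GR against R (-0.11 and 0.28 with the trend removed, percentiles 0.00 and 76.9). Of 30 tested DNA damage genes 1 was called lower for R over all genes (8 lower and 0 higher adjusted over the list alone). Their medians were -0.19 in TR against T and -0.31 in GR against G (-0.03 and -0.35 with the trend removed, percentiles 89.9 and 0.00). Nucleic acid sensing genes had medians of 0.02, 0.31 and -0.25 in T, G and R against control. In the same pairs, apoptosis genes had medians of -0.01, 0.23 and -0.01 (0.09 for R with median-ratio scaling). Epithelial genes had 0.07, 0.41 and 0.23 and endothelial markers -0.09, -0.16 and 0.23. With the trend removed these were 0.04, 0.19 and -0.36 for nucleic acid sensing, 0.05, 0.21 and 0.06 for apoptosis, 0.20, 0.58 and 0.15 for epithelial genes and 0.08, -0.05 and 0.22 for endothelial markers. Of 30 tested apoptosis genes 2 were called higher for R over all genes (3 higher and 2 lower adjusted over the list alone). Of 5 tested leukocyte markers none was called for R, T or G by edgeR, and for G their median log2 fold change was 2.11 (camera adjusted p = 0.75 with a preset correlation, adjusted p = 0.952 with an estimated correlation), with 1 lower adjusted over the list alone.

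The loss of mitochondrially encoded RNA with R was uneven between genes. An equal loss of all of it, such as by scaling or yield, would give similar falls, but the SD between the 13 mRNAs was 3.67 times the residual SD. That argues against an equal loss as the whole cause, not as a part of it. The test left out the ribosomal RNAs, of which MT-RNR1 did not fall (0.25 ± 0.34) and MT-RNR2 did (-2.21 ± 0.43; SD, n = 3 pairs). An equal part would have to be offset in MT-RNR1, which was not tested. Whether fewer mitochondrial genomes would lower each RNA equally is not shown by these libraries, so that cause stays open. The GC and length trend of nuclear genes predicted a median of -0.06, against -4.83 observed. A loss that grows with distance from the heavy-strand promoter may contribute, with a Spearman correlation of -0.47 over 14 RNAs (permutation p = 0.095) and of -0.15 over the 12 mRNAs (permutation p = 0.636), which leaves it open. Changes in transcription, RNA stability or polyadenylation, which oligo(dT) capture would read as a loss, were not tested.

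The mitosis list was low in T against control and not in TR against R. The difference of its medians was 1.54 with the GC and length trend removed, so that trend does not account for it, and the median of 0.06 in R against control (0.01 with the trend removed) argues against mitosis genes already low with R alone, while S phase genes were low with R alone (-0.58, percentile 0.00). TR may be a second R library, mislabelled or without T, and of genes with a symbol and no overlap 5 differed 2-fold the same way in both pairs (chance 0.56) and 1 the opposite way (chance 0.64; exact sign test p = 0.219), so this cannot be told apart from an effect of R on the response to T. The medians of heat shock (-0.31, and -0.68 in T against control), NF-kB (0.51 and 0.37) and secretory genes (0.38 and 0.26) in TR against R lay in the direction of T against control. Those of ribosomal protein (-0.06 and 0.21), mitochondrially encoded (0.16 and -0.48) and cholesterol synthesis genes (0.15 and -0.52) lay in the other direction. The ratios of all genes correlated at r = -0.086, but the pairs had opposite trends with GC content. This value therefore does not weigh for or against T in TR. KRT85 and the readthrough gene RPL36A-HNRNPH2 speak against a TR library without T, with 0 counts in the control and R, 4067 and 543 in T and 5076 and 408 in TR, and KRT85 had 1333 in G and 3310 in GR, but genes at 0 in a pair of these 4 libraries and at 100 counts or more in the other pair numbered 3 along T (with ISY1-RAB43), 0 in the reverse and 2 and 2 in the arrangements that do not follow T (WASH2P, GTF2IP4, BLOC1S5-TXNDC5 and 1 without a symbol, all named after their values were seen).

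Secretory and NF-kB genes were higher with G without and with R. With the GC and length trend removed, the lowest percentile of the 4 medians was 99.32, which argues against that trend as the cause. Of 6 abundant leukocyte transcripts 0 reached an FPKM of 1 in G or GR (5 had a value, the highest 0.533), which argues against leukocytes in these cultures. An inflammatory response to G is a hypothesis that these libraries could raise but not settle, since a mislabelled library or a difference between single cultures was not tested. By source name G against control also changes cell line, while GR against R does not, although the low ERBB2 levels argue against SKOV3 cells.

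For the genes called for R, 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave 523 genes, and the highest of the others gave 0. With 10 splits the share is never under 0.05. In the other splits the difference between libraries with and without R enters the residual spread, which works against calls. The comparison of splits therefore decides nothing.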
